A study of Mus musculus with 4 samples.

How the data were processed

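RNA was measured in 4 libraries labelled as mouse skin regulatory T cells, 2 without and 2 with UVB. Per the labels' protocols, libraries were made with an ultra-low-input SMARTer kit from total RNA and sequenced as single-end reads of 100 bp. How the cells were sorted and the strandedness of the libraries are not given in the sources used here, so overlapping and antisense genes cannot be separated. Per the submitters' processing notes, HISAT2, StringTie and DESeq2 were used with GRCm38 (mm10), with no version or role given, and the gene annotation version is likewise not given. Per the file headers, the authors deposited 1 gene abundance table per library with gene ID, name, position, coverage, FPKM and TPM. Deposited coverage is the mean read depth per base of a gene, not scaled to library size. Deposited FPKM is scaled to gene length and to a total per library, and deposited TPM has the same total of 1000000 in every library.

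Rows of 1 gene ID were summed and the tables joined on the gene ID, which gave 55487 genes. Of these IDs, 55227 were found in GENCODE M21, used only for gene types, lengths and ubiquitous gene classes, and 54907 had the same coordinates there. By the definition of FPKM, the highest ratio of coverage to FPKM in a library gives the bases behind its FPKM values. These were 3.41 and 2.47 gigabases in non-UVB replicates 1 and 2 and 4.20 and 2.38 gigabases in UVB replicates 1 and 2. Whether they are all sequenced bases or only aligned ones is not given in the sources used here. A gene of 1 kb with 1 read would have 0.0442 and 0.0583 TPM in the former and 0.0369 and 0.0612 TPM in the latter. Whole reads were not recovered, because coverage holds fractions of reads, so no test on read numbers was run and no counting interval is given. The median SE of a log2 difference was 1.12.

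Genes with at least 1 TPM in at least 2 of the 4 libraries were tested, 10286 in all, of which 7627 were protein-coding. Values were log2(TPM + 1), so a difference on this scale understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3, with group as the only term and an intensity trend in the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 where at least 5 members were tested. Of 37 lists 30 were tested, and adjustment ran over the 30. Of 722 list members, 2 were not found. Camera was also run with an estimated correlation, and fry was run on the same lists. With an estimated correlation all 30 lists had a camera adjusted p of 0.99. T cell receptor activation genes went from an unadjusted camera p of 0.0075 to 0.099, although their estimated correlation was -0.02, below the preset value. A call lost there therefore cannot show that correlation between genes explains the call. Random lists matched on abundance, 10000 for each list, gave the percentile of each list's median. The design written beforehand allowed for read numbers, and limma was used because the files hold TPM.

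The rule for named genes was fixed before the data were examined. It took 13 genes of regulatory T cell and type 17 biology whatever their result, then the 10 genes in each direction with the highest change among those past the threshold or, where none passed, with the smallest unadjusted p. Predicted genes, Rik, mitochondrial, ribosomal protein, immunoglobulin and receptor V genes were left out there. It also took up to 2 members per direction of each list described and the 2 most abundant members of each list of another cell type. Genes outside the rule are said to be so where they are named, and some genes that the rule takes are not reported here.

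The test was run on simulated data with the genes and spread of these libraries. With 200 of 10286 genes changed by 2, 4 or 6 log2, limma called 0 at an adjusted p under 0.05, and 28.5%, 71% and 86.5% of the changed genes had an unadjusted p under 0.05. Camera called the cell cycle list of 35 genes when it was shifted by 1 or 2 log2, and called no other list. Simulated genes varied independently, so this does not show how often camera calls lists whose genes move together. The estimated correlation was 0.476 for the macrophage list and 0.986 for the mitochondrially encoded list.

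Alternatives changed the pseudocount, the filter, the unit, the scaling, the genes behind the TPM total, the spread model, the threshold, the set test and the list size, added the replicate number as a block, and left out each library in turn. When 1 library was left out, the lone library was assumed to vary like the other group. The filter of 1 TPM in 2 libraries was then applied again to the libraries that remained. Genes at 1 TPM or more only in the group that lost a library therefore dropped out. Added after seeing the data were TPM without haemoglobin, protein-coding genes only, genes with a mean of at least 50 TPM, and the libraries of each number alone. The sum of a list is its members' TPM in a library. Entropy of V segments was computed from TPM within alpha and beta segments. Figures were drawn with matplotlib 3.10.9.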

Results

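Cells labelled as regulatory T cells from the skin of mice with psoriasiform dermatitis were profiled by RNA sequencing, with or without narrow-band ultraviolet B (UVB). Regulatory T cells are CD4 T cells that restrain immune responses and are defined by the transcription factor Foxp3. Dermatitis was induced by daily application of 60 mg of a cream with 5% imiquimod, an agonist of the RNA sensor TLR7, and the irradiated animals received 3 exposures to UVB. The design comprised 4 libraries, 2 from non-irradiated and 2 from irradiated mice, numbered 1 and 2 within each group. The study asked how UVB alters skin regulatory T cells, whose peripheral induction is named in its title. The FPKM values rested on about 34100000 and 24700000 reads of 100 bp in non-UVB replicates 1 and 2, and on 42000000 and 23800000 in UVB replicates 1 and 2. No source says that the replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

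Several T cell transcripts differed along the replicate number. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, GRCm38) was listed at 0 TPM in non-UVB replicate 1 and at 3.49 TPM in UVB replicate 1, against 19.4 and 19.3 TPM in non-UVB and UVB replicate 2. Ikzf2, which encodes the regulatory T cell factor Helios, stood at 0.068 and 17.6 TPM in the libraries numbered 1 and at 303 and 170 TPM in those numbered 2, non-UVB first. Ctla4, an inhibitory receptor, had 314 and 548 TPM against 1496 and 1473 TPM, and Il10 had 38.1 and 87.6 TPM against 319 and 288 TPM. Il17a, a type 17 cytokine, went the other way, with 2330 and 1995 TPM in the libraries numbered 1 against 904 and 799 TPM in those numbered 2. Not all genes of regulatory T cells followed the number. Il2ra had 248 and 134 TPM against 252 and 176 TPM, and Icos had 1221 and 784 TPM against 826 and 620 TPM. CD4 T cell markers summed to 9448 and 8178 TPM against 9519 and 6423 TPM. Members of that list differed in opposite ways. The alpha receptor constant gene Trac, chosen after its values were seen, had 274 and 554 TPM against 2350 and 878 TPM. The beta constant gene Trbc1 had 1386 and 809 TPM against 830 and 462 TPM. The sum therefore does not show equal shares of CD4 T cells.

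Genes of the gamma-delta T cell receptor were also higher in the libraries numbered 1. Of the list of gamma-delta T and innate lymphoid markers, Trdv4 (chromosome 14, 54074905 to 54075515) was at 4422 and 3531 TPM in non-UVB and UVB replicate 1 and at 119 and 159 TPM in replicate 2, and Trgc1 was at 1884 and 2575 TPM against 4.86 and 8.15 TPM. The list summed to 10013 and 9175 TPM in the libraries numbered 1 and to 284 and 538 TPM in those numbered 2. The delta constant gene Trdc and the alpha constant gene Trac, chosen after their values were seen, stood in a ratio of 5.08 and 2.14 in the libraries numbered 1 and of 0.0206 and 0.0816 in those numbered 2. Keratinocyte markers summed to 555 and 780 TPM against 5275 and 5927 TPM, with Krt14, a keratin of basal keratinocytes, at 101 and 214 TPM against 1527 and 1232 TPM. Mitochondrially encoded genes took 0.857% and 0.487% of TPM against 5.73% and 6.42%. Haemoglobin genes took 11.7% of TPM in non-UVB replicate 1 and between 0.153% and 0.441% in the other 3 libraries.

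**Figure D1:**
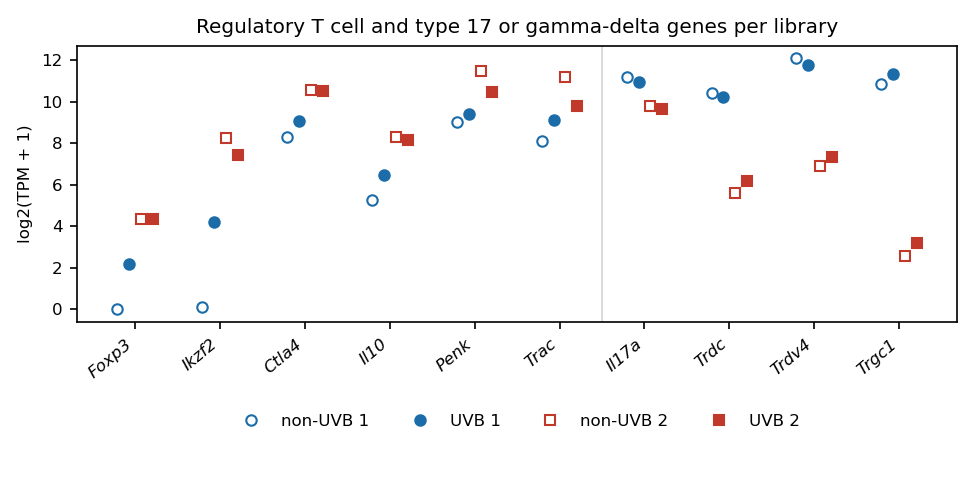
Each point is 1 library's log2(TPM + 1) for a gene on the horizontal axis. Circles are libraries numbered 1 and squares those numbered 2, open for non-UVB and filled for UVB. Genes to the left of the line, such as Ikzf2, are higher in the squares, and those to its right, such as Trdc, are higher in the circles.

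The first comparison asked which genes differed with UVB. Among genes with the smallest unadjusted p, Snrnp25, a subunit of the minor spliceosome, was listed at 0 and 0.718 TPM in non-UVB replicates 1 and 2 and at 172 and 193 TPM in the UVB libraries. Rnf130, a RING-finger protein, was at 0.028 and 0.137 TPM against 191 and 116 TPM, and Rcan1, an inhibitor of calcineurin, was at 0 and 0.118 TPM against 76.4 and 125 TPM. In the opposite direction, Cars, a cysteinyl-tRNA synthetase, was at 112 and 157 TPM in the non-UVB libraries and at 0.075 and 0.286 TPM in the UVB libraries. Zbp1, a sensor of Z-form nucleic acid, was at 65.0 and 106 TPM against 0.067 and 0.685 TPM. On the log2(TPM + 1) scale the differences were 7.12 ± 1.05 (SE, n = 2 per group) for Rnf130 and -6.83 ± 1.04 for Cars. None of these genes passed the test, since each had a limma adjusted p of 0.223 after Benjamini-Hochberg adjustment over 10286 genes.

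The other genes named by the same rule were Zfp672, Srrd, Haus1, Tamm41, Tmem107, Polr1c and Cd244a on the higher side and Nsun6, Nup43, Mapk1ip1, Zfp51, Tmem80, Snhg4, Trmt10b and Stom on the lower side. Srrd, Tamm41 and Tmem107 were listed at 0 in both non-UVB libraries, and Nup43 and Trmt10b at 0 in both UVB libraries. With limma, 0 genes had an adjusted p under 0.05, and 1167 had an unadjusted p under 0.05, 1026 higher and 141 lower with UVB, where chance gives 514.3. Splitting the libraries by replicate number gave 1290 such genes, more than UVB did, and the crossed split gave 585. With 1 library left out, most such genes were lower without either UVB library and higher without either non-UVB library. The filter alone favours this, since genes at 1 TPM or more only in the group that lost a library were no longer tested. At 2524 genes the UVB and non-UVB libraries did not overlap and the group means differed by at least 1 log2, 1859 higher and 665 lower with UVB. At any size of difference 32.9% of genes were separated, and chance gives 33.3%. Quantile normalization turned the balance of separated genes, with 45.0% of them higher with UVB against 73.7% as measured, and median scaling gave 58.0%. In simulated libraries with the same spread, limma called none of 200 genes even at a change of 6 log2, so a count of 0 does not show that genes were alike.

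More genes were detected with UVB. At 1 TPM or more, 10317 and 10227 genes were detected in the UVB libraries against 7825 and 8033 in the non-UVB libraries, a mean of 10272 ± 63.6 against 7929 ± 147 (SD, n = 2 per group). The exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries allow. Genes at 1 TPM or more in both UVB libraries and below it in both non-UVB libraries numbered 1037, and 126 genes showed the opposite. Splitting by replicate number gave 513 such genes present in number 2 alone and 511 in number 1 alone. The crossed split, UVB 1 and non-UVB 2 against the others, gave 372 and 299. Such genes thus also arose in splits that do not follow UVB, a limit on all genes named below that were near 0 in 1 group. The median tested gene was 0.26 log2 higher with UVB, and it lay at -0.19 after quantile normalization and -0.15 after median scaling. It was 0.06 without non-UVB replicate 1 and 0.40 without UVB replicate 1. For the main lists, medians are also given relative to all genes. Of 218 genes of ubiquitous complexes such as the proteasome and the mitochondrial ribosome, 43 and 50 were under 1 TPM without UVB and 13 and 18 with it, and 24, 9, 9 and 5 were listed at 0 in non-UVB 1, UVB 1, non-UVB 2 and UVB 2. A gene listed at 0 is therefore described only as such.

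The second comparison asked which fixed gene lists differed with UVB. Markers of macrophages and dendritic cells had higher means with UVB for 17 of 20 tested members, and 13 were higher within both replicate numbers. H2-Eb1, an MHC class II chain, had 270 and 258 TPM without UVB and 629 and 771 TPM with UVB, a difference of 1.39 ± 0.34 log2. Cd74, the MHC class II invariant chain, had 3101 and 1940 TPM against 4237 and 3838 TPM, a difference of 0.72 ± 0.34, and Tyrobp, a myeloid signalling adaptor, differed by 0.90 ± 0.42. Among the lower members, Ccl22, a chemokine of dendritic cells, was at 0.031 and 168 TPM without UVB and at 0 and 11.9 TPM with UVB, and Cst3, a cysteine protease inhibitor, differed by -0.07 ± 0.35. The list's median was 1.14 log2 higher with UVB, 0.88 above that of all genes, at 0.54 in the libraries numbered 1 and 1.69 in those numbered 2.

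This list did not pass camera's test at the preset correlation (adjusted p = 0.133), and its adjusted p was 0.99 with an estimated correlation. It passed after quantile normalization (adjusted p = 0.0247) and among genes with a mean of at least 50 TPM (adjusted p = 0.00010), the latter a setting chosen after seeing the data, and also without non-UVB replicate 1 (7.5e-05) or UVB replicate 2 (2.7e-06). Without non-UVB replicate 2 its median was 0.23, a difference of -0.03 from that of all genes (adjusted p = 0.929). No member passed adjusted over the list alone or over all genes.

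Immediate early and dissociation stress genes, which respond within minutes to stimulation and tissue handling, formed the 1 list past the threshold (camera adjusted p = 0.0148). The call was lost when the correlation was estimated (camera adjusted p = 0.99). Every list tested had that value there, so the loss does not show that correlation explains the call of this list. Of its 28 members, 22 had a lower mean with UVB, 9 of them lower within both replicate numbers, and none passed over all genes or adjusted over the list alone. Btg2, an antiproliferative gene induced by p53, had 385 and 525 TPM without UVB and 131 and 173 TPM with UVB, a difference of -1.57 ± 0.43 log2. Fos had 712 and 1071 TPM against 576 and 525 TPM, a difference of -0.67 ± 0.37, while Atf3 stood at 0.84 ± 1.04 and Ier5 at 0.44 ± 0.45. The list's median was -0.19 log2, 0.45 below that of all genes. The median was -0.38 and -0.04 without non-UVB replicates 1 and 2, and -0.41 and -0.30 without UVB replicates 1 and 2. It was at -0.03 in the libraries numbered 1 and -0.54 in those numbered 2, or -0.30 and -0.71 relative to all genes in the same libraries. Myeloid markers, whose list did not pass as given above, summed to 14990 and 6712 TPM without UVB and to 24993 and 14983 TPM with it. These sums were higher with UVB within each replicate number, but UVB replicate 2 did not exceed non-UVB replicate 1. The call also ended without non-UVB replicate 2 (adjusted p = 0.390), after quantile normalization (0.341) and without the intensity trend (0.120).

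**Figure D2:**
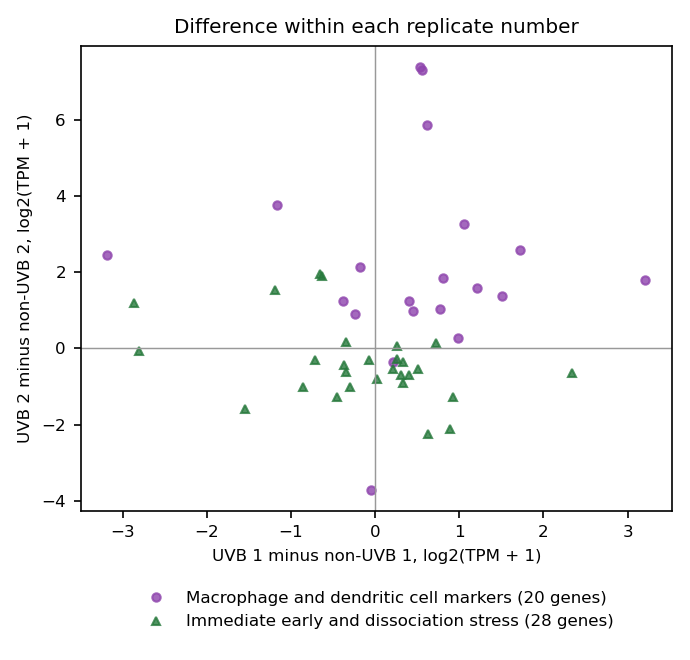
Each point is a gene, with the UVB minus non-UVB difference in log2(TPM + 1) in the libraries numbered 1 on the horizontal axis and in those numbered 2 on the vertical axis. Macrophage and dendritic cell markers (purple circles, 20 genes) had medians of 0.54 and 1.69, and immediate early and stress genes (green triangles, 28 genes) had medians of -0.03 and -0.54.

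Genes of T cell receptor activation had lower means with UVB for 13 of 21 members and a median of -0.57 log2, -0.83 relative to all genes (camera adjusted p = 0.112, and 0.99 with an estimated correlation), at -0.20 and -0.52 within the replicate numbers. Nr4a1, a nuclear receptor induced by antigen receptor signalling, had 857 and 747 TPM without UVB and 370 and 249 TPM with UVB, a difference of -1.40 ± 0.38. Egr2 stood at 2.25 ± 1.22 and Dusp5 at 0.34 ± 0.57. The list passed without non-UVB replicate 1 (adjusted p = 0.0433), without UVB replicate 2 (0.00619) and among genes with a mean of at least 50 TPM (0.0311). It did not pass without UVB replicate 1 (median -0.10, adjusted p = 0.211), without non-UVB replicate 2, where the median turned to 0.04 (0.390), or after quantile normalization (0.341). CD4 T cell markers had 11 of 16 lower means and a median of -0.25, -0.51 relative to all genes (adjusted p = 0.133), beside macrophage and dendritic cell markers at a median of 1.14. The median was -0.49 and -0.43 without non-UVB replicates 1 and 2. Trbc2 stood at -0.55 ± 0.28 and Trbc1 at -0.81 ± 0.49, 2 constant genes of the beta chain that share near-identical sequence. Among the higher members, the adhesion receptor Cd2 was at 1.56 and 1264 TPM without UVB and at 490 and 877 TPM with UVB, a difference of 3.53 ± 3.24, and Ptprc, which encodes CD45, differed by 0.36 ± 0.52. The mean of the list was -0.002.

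Treg identity genes had a lower mean with UVB for 11 of 17 members and a median of -0.13 log2, -0.39 relative to all genes (camera adjusted p = 0.267, and adjusted p = 0.99 with an estimated correlation). The median was -1.10 without non-UVB replicate 1, -0.06 without UVB replicate 1 and -0.29 without UVB replicate 2, and it turned to 0.72 without non-UVB replicate 2. The median had opposite signs within the replicate numbers, 0.28 in those numbered 1 and -0.52 in those numbered 2. Il2ra, the high-affinity interleukin-2 receptor chain, had 248 and 252 TPM without UVB and 134 and 176 TPM with UVB, a difference of -0.70 ± 0.42. The costimulatory receptor Icos stood at -0.53 ± 0.37, Foxp3 at 1.08 ± 2.02, Ctla4 at 0.39 ± 0.99 and Ikzf2 at 1.64 ± 3.21. Nrp1 was at 0.023, 29.5, 1.28 and 0.319 TPM in non-UVB 1, UVB 1, non-UVB 2 and UVB 2. The thymic markers had a median of 0.00 and the peripheral markers one of 0.52, with camera adjusted p = 0.874 and 0.957. The thymic median was -1.22 without non-UVB replicate 1 and 0.60 without UVB replicate 1, and too few members were tested without non-UVB replicate 2. The peripheral median turned to -0.28, -0.44 and -0.15 without non-UVB replicate 1, UVB replicate 1 and non-UVB replicate 2, and was 0.07 without UVB replicate 2.

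Suppressive mediators had 14 of 21 members with a higher mean and a median of 0.31, or 0.05 relative to all genes, although camera set the list below other genes (adjusted p = 0.893). The median turned to -0.74 without non-UVB replicate 1 and to -0.17 without UVB replicate 2, and was 0.74 without UVB replicate 1. Entpd1, the ectonucleotidase CD39, was at 0.039 and 0.355 TPM without UVB and at 44.6 and 50.2 TPM with UVB, and Prdm1, which encodes Blimp-1, was at 0.027 and 0.80 TPM against 31.9 and 10.7 TPM. Fgl2 stood at -1.35 ± 0.57, Tgfb1 at 0.37 ± 0.58 and Il10 at 0.52 ± 1.32. Tissue repair genes had a median of 0.23, or -0.03 relative to all genes (adjusted p = 0.874), which turned to -0.27 without non-UVB replicate 1, was 0.003 without UVB replicate 2 and was 0.49 without non-UVB replicate 2. Of these, Pparg, a regulator of lipid metabolism and of tissue regulatory T cells, was listed at 0 in both non-UVB libraries and at 21.9 and 31.6 TPM with UVB, while Areg stood at -0.46 ± 0.51, Il1rl1 at -2.08 ± 1.20 and Penk, the proenkephalin gene, at -0.31 ± 0.99. Penk had 529 and 2875 TPM without UVB and 684 and 1441 TPM with UVB. Ccr8, a chemokine receptor of skin T cells, stood at -0.11 ± 0.60.

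Type 17 genes had a median of 0.00 (adjusted p = 0.707), with Il17a at -0.20 ± 0.73. The libraries pulled this median opposite ways, to 1.09 and 1.27 without non-UVB replicate 1 and UVB replicate 2 and to -0.27 and -1.43 without UVB replicate 1 and non-UVB replicate 2. Genes of the p53 response had a median of 0.87, or 0.61 relative to all genes, and 15 of 21 higher means (adjusted p = 0.574), and a median of 0.42 without non-UVB replicate 1. Fas, a death receptor, was at 0.064 and 0.793 TPM without UVB and at 104 and 24.5 TPM with UVB, while Btg2, with the values above, is in this list as well. Genes of the unfolded protein response had a median of 0.96, or 0.70 relative to all genes, and 13 of 18 higher means (adjusted p = 0.707), with Manf, an endoplasmic reticulum stress protein, at 1.29 ± 0.44. The median was 0.52 without UVB replicate 1 and 0.15 without non-UVB replicate 2, the latter -0.10 relative to all genes. Ddit3, which encodes CHOP, was at 61.1 and 98.6 TPM without UVB and at 0 and 52.2 TPM with UVB, and Xbp1 stood at -0.74 ± 0.59.

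Cell cycle genes had a median of 0.60, or 0.34 relative to all genes, and 24 of 35 higher means (adjusted p = 0.874), but a median of -0.20 without non-UVB replicate 2 and 1.24 without UVB replicate 2. Aurka, a mitotic kinase, was at 0 and 0.224 TPM against 35.7 and 33.4 TPM, while Gins2, a replication factor, differed by -2.06 ± 1.05. The type I interferon response had a median of -0.33, or -0.59 relative to all genes (adjusted p = 0.357), which turned to 0.86 without UVB replicate 1, 0.13 with no filter and 0.10 with a pseudocount of 0.1. Oas1a, an antiviral enzyme, was listed at 0 in both non-UVB libraries and at 30.7 and 3.92 TPM with UVB, while Bst2, which tethers enveloped viruses, differed by -3.12 ± 1.26. Th1 genes had a median of -0.21 and 7 of 11 lower means (adjusted p = 0.444), with a median of -1.17 without non-UVB replicate 1 and 0.34 without UVB replicate 2. Of these, Stat4 stood at -3.11 ± 1.80, while the chemokine Ccl4 had 417 and 415 TPM without UVB and 1780 and 1219 TPM with UVB, a difference of 1.82 ± 0.35.

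Among other cell types, 3 of 10 tested neutrophil markers passed adjusted over the list alone and 0 over all genes, all 3 higher with UVB. The list itself did not pass (camera adjusted p = 0.653), with 3 members higher and 4 lower within both replicate numbers. Its median of 0.92 was -0.02 and 0.92 without non-UVB replicates 1 and 2, and 0.89 and 0.06 without UVB replicates 1 and 2. Trem1 was at 0 and 0.063 TPM without UVB and at 20.1 and 13.9 TPM with it, Clec4d was listed at 0 in both and at 81.2 and 26.7 TPM, and Clec4e, chosen after its values were seen, was at 5.09 and 0.243 TPM against 107 and 150 TPM. These 3 genes encode innate receptors that macrophages also express. S100a8, the abundant neutrophil alarmin, had 257 and 2249 TPM without UVB and 252 and 1455 TPM with UVB, a difference of -0.33 ± 1.47. Keratinocyte and gamma-delta lists had medians of 0.38 and 0.24 with camera adjusted p = 0.893 and 0.878. The keratinocyte median was 2.41 and 1.87 without UVB replicate 1 and non-UVB replicate 2, and -1.43 and -0.82 without non-UVB replicate 1 and UVB replicate 2. The gamma-delta median was 4.07 and 3.08 without non-UVB replicate 1 and UVB replicate 2, and -1.86 and -3.42 without UVB replicate 1 and non-UVB replicate 2. Too few members were tested in 7 lists, among them fibroblast markers, which summed to between 51.4 and 186 TPM, endothelial markers, between 7.39 and 133 TPM, and B cell markers, between 524 and 819 TPM.

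The third comparison described the use of T cell receptor V segments, for which no test was made. Beta V segments were detected at 8 and 12 of 35 in non-UVB replicates 1 and 2 and at 13 and 18 in UVB replicates 1 and 2. Their entropy, which is higher when use is more even, was 2.17 and 2.88 bits without UVB and 3.24 and 2.58 bits with it. Trbv13-2 held the largest share of beta V signal in non-UVB replicate 1 (46.1%) and UVB replicate 2 (47.8%), against Trbv19 in UVB replicate 1 (23.1%) and Trbv12-1 in non-UVB replicate 2 (22.1%). Alpha V entropy was 2.69 and 4.19 bits without UVB and 4.47 and 4.01 bits with it. It rested on totals of 201 and 1050 TPM without UVB and 297 and 589 TPM with it. The top segments of the libraries numbered 1 were Trav14d-3-dv8 (26.3%, non-UVB) and Trav4-4-dv10 (10.3%, UVB), which are named for delta as well as alpha chains. Alpha entropies are therefore not directly comparable between the libraries. Within the replicate numbers the beta entropy was higher with UVB in those numbered 1 and lower in those numbered 2, and so was the alpha entropy. Segments with near-identical copies share reads, so single alpha segments are uncertain.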

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

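The alternatives were fixed before the data were examined, except those without haemoglobin genes, with protein-coding genes only, with abundant genes only and with the libraries of each number alone, which were chosen after seeing the data. With limma, 0 genes had an adjusted p under 0.05 in every one of the 18 settings run on genes, and 0 at an adjusted p under 0.1. The smallest adjusted p ranged from 0.136 to 0.9999, and the number of genes at an unadjusted p under 0.05 was 1167 as measured, 977 with no filter, 1187 with a pseudocount of 0.1 and 33 without UVB replicate 2. A count of 0 in this design says nothing about stability. An edgeR test was planned only for files with read numbers and was not run, and neither was DESeq2.

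The separated genes numbered 2524. They numbered 470 among genes with a mean of at least 50 TPM, where fewer genes were tested, and 5201 and 5576 in the libraries numbered 1 and 2 alone, where 1 library per group cannot overlap. They ranged from 2688 to 4879 when 1 library was left out, the highest without non-UVB replicate 1, with 4673 without non-UVB replicate 2. Of the genes at an unadjusted p under 0.05, 87.9% were higher with UVB, against 70.4% after quantile normalization and 78.3% after median scaling. The direction turned when a UVB library was left out and held when a non-UVB library was. The filter, applied again, left 8366 and 8437 genes without UVB replicates 1 and 2. It left 9350 and 9275 without non-UVB replicates 1 and 2. Genes at 1 TPM or more only in the group that lost a library were removed, so this contrast cannot be told apart from the filter. Of the separated genes, 60.8% to 62.0% were higher with UVB when 1 library was left out.

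The lists past the threshold numbered 1 as reported. They numbered 2 with no filter, 0 without the intensity trend, 3 among abundant genes, 0 with an estimated correlation and 0 with fry's directional test, and the cause was not tested. Fry's mixed test, for change in either direction, passed 8 lists. They ranged from 0 to 7 when 1 library was left out, with 5 without non-UVB replicate 1, 5 without UVB replicate 1, 0 without non-UVB replicate 2 and 7 without UVB replicate 2. Besides lists already named, they included mitochondrially encoded genes, lower with UVB without non-UVB replicate 1 (median -1.92) and UVB replicate 2 (-2.06) but higher without UVB replicate 1 (1.57). They also included keratinocyte genes, higher without UVB replicate 1 (2.41) and lower without UVB replicate 2 (-0.82), TGF-beta response and chemokine receptor genes without UVB replicate 1, and cell cycle and gamma-delta genes without UVB replicate 2. The adjusted p of the stress list ranged from 0.00019 after median scaling to 0.390 without non-UVB replicate 2, apart from the other set tests.

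With the replicate number as a block, 0 genes and 5 lists passed, namely macrophage (adjusted p = 0.00377), stress (0.00377), T cell receptor activation (0.0343), CD4 T cell (0.0457) and mitochondrially encoded genes (0.0469). With an estimated correlation each had adjusted p = 0.988 with the block and 0.99 without it, and so had every other list tested. The labels tie these libraries by a number alone, although their content differed along it, as in the gamma-delta and keratinocyte genes above. Splitting by number gave 1290 genes at an unadjusted limma p under 0.05, against 1167 for UVB. The deviations from the group means correlated at 0.165 across genes. Of 149 named genes, 45 changed sign when 1 library was left out and 12 under another setting, and none passed the threshold in any. Shares of gene classes are the same in FPKM by construction. The excess of genes detected with UVB held at limits of 0.1 and 5 TPM. Depth limits values near 0.0369 to 0.0612 TPM, what 1 read over 1 kb is worth.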

Other observations

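Of the tests below, those of ubiquitous genes and of haemoglobin in the detected genes were written before their results were seen, and the others after.

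With all 4 libraries, lists not described above had medians within 1 log2 of 0, except the response to AhR and vitamin D, at 2.55 over 6 tested members with 5 higher means (camera adjusted p = 0.413) and at 1.53 with no filter. With 1 library left out others passed that range. Without non-UVB replicate 2, naive T cell genes were at 2.56 and apoptosis regulators at 1.12. Without UVB replicate 1, naive T cell genes were at 1.01 and Th2 genes at 1.08, and without UVB replicate 2 lipid genes were at 1.25. Ahr, the aryl hydrocarbon receptor, was at 0.042 and 6.17 TPM without UVB and at 67.0 and 25.8 TPM with UVB. Apoptosis regulators had a median of 0.75 and 12 of 17 higher means (adjusted p = 0.413), and a median of 0.44 without non-UVB replicate 1 and 0.26 after quantile normalization, with Casp8, an initiator caspase, at 0.215 and 1.49 TPM against 116 and 45.3 TPM and Xiap, a caspase inhibitor, at -1.98 ± 1.82. TGF-beta response genes had a median of -0.42 (adjusted p = 0.368), which was -0.80 without non-UVB replicate 1, -0.82 without UVB replicate 1 (adjusted p = 0.0260), 0.05 without non-UVB replicate 2 and 0.03 without UVB replicate 2. Of these, Tgif1, a repressor of Smad signalling, was at 189 and 267 TPM against 84.7 and 104 TPM, and Cd101, an inhibitory receptor, was at 0 and 0.130 TPM against 24.0 and 19.5 TPM. Chemokine receptors and homing genes had a median of -0.33 (adjusted p = 0.357), which was -0.42 without UVB replicate 1 (adjusted p = 0.0160) and -0.56 without non-UVB replicate 2, and turned to 0.02 and 0.10 without non-UVB replicate 1 and UVB replicate 2. The homing receptor gene Gpr15 stood at -4.23 ± 1.82, and the receptor gene Il6ra of the naive T cell list was at 17.3 and 10.6 TPM against 0.016 and 0.302 TPM. Against random lists matched on abundance, the medians of the macrophage and unfolded protein response lists lay at percentiles of 100 and 99.93, and that of the T cell receptor activation list at 0.04, as a description of these libraries.

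The first pattern was that genes of the gamma-delta receptor were high and Foxp3 low in the libraries numbered 1, in both groups. Of the 7 tested list members that are no receptor genes, 5 (71.4%) were higher in both libraries numbered 1 than in both numbered 2 and 1 was lower in both. Chance gives 16.7% for genes that vary independently, which these need not do, and the list was already seen to be high there. Of the 5, Il23r and Blk are also in the type 17 list, so they cannot tell gamma-delta T cells from other type 17 cells. Gamma-delta T cells among the collected cells are a candidate explanation, at the Trdv4 and Trgc1 levels given above. Regulatory T cells with alpha-beta receptors that express type 17 genes would keep Trdc below Trac, and the lower ratio of the libraries numbered 1 was 2.14. This argues against them as the whole source, on 2 genes chosen after their values were seen. The beta constant genes did not fall with Trac. Trbc1 had 1386 and 809 TPM in the libraries numbered 1 against 830 and 462 TPM, and Trbc2 had 1418 and 910 TPM against 1405 and 1026 TPM. The share of alpha-beta T cells in those libraries stays open. Of the 16 list members 4 also stand in another list, namely Il23r, Blk, Gzma and Kit, all of them among the 7 above. The gate that would remove gamma-delta T cells is not given in the sources used here. A difference in sorting, in animals or in a wrong label stays open.

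The second pattern was that more genes were detected with UVB. Depth, taken as the reads behind the FPKM values, is argued against. UVB replicate 2 differed by -0.84 Mreads (1 Mread is 1000000 reads) from non-UVB replicate 2. It also had fewer such reads than non-UVB replicate 1, yet more genes than both. Haemoglobin reads are argued against as well, since without them non-UVB replicate 1 still had 2322 fewer genes at 1 TPM than the lower UVB library. Of 218 ubiquitous genes, 19.7% and 22.9% were under 1 TPM in the non-UVB libraries against 5.96% and 8.26% in the UVB libraries, a difference of 14.2 percentage points, as a loss of transcripts from the non-UVB libraries, for example by fewer cells, may give. Whether UVB itself raised the number of genes expressed was not tested and stays open.

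The third pattern was the list of immediate early and stress genes, of which 22 of 28 had a lower mean with UVB. Within the replicate numbers, 14 of 28 were lower in those numbered 1 and 21 in those numbered 2. No member passed, and camera's call was lost with an estimated correlation (adjusted p = 0.99), a value that every list tested had there. The upward shift of low genes stays open, since quantile normalization took the list's median relative to all genes from -0.45 to -0.01 and ended the call (adjusted p = 0.341), although the median lay at percentiles of 0.89 and 1.24 among random lists matched on abundance before and after it. Whether the libraries numbered 2 alone carry the pattern stays open, since the list's median relative to all genes was -0.30 in those numbered 1 and -0.71 in those numbered 2, at percentiles of 8.47 and 0.04 among such random lists. Dilution of T cell transcripts by added myeloid cells cannot be told apart from a change of the stress genes, since the T cell list's median lay at most 0.053 above that of the stress list in either number. Drawing the genes again 2000 times gave intervals of -0.84 to 0.60 and -0.29 to 0.44 for the difference. These intervals treat genes as independent and hold no spread between libraries. An effect of UVB stays open and untested.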
